A study of Mus musculus with 38 samples.

How the data were processed

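Gene expression was measured with Affymetrix arrays in whole brain and liver of C57BL/6J mice, an inbred laboratory strain, after 30 days of haloperidol from slow-release pellets or of placebo. The 38 arrays comprised 10 haloperidol and 10 placebo brains, and 9 haloperidol and 9 placebo livers, each array from the tissue of 1 mouse per the series' design text. Tissues were dissected, snap-frozen and pulverized, and total RNA was labelled with biotin, per the labels' protocols. The array model, the hybridisation dates and any filter on arrays or probes are not given in the sources used here.

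The deposited values are on a log2 scale and were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no versions for them. RMA corrects the background, gives the arrays a common distribution of probe values and summarises the probes of a probe set, so a change of total RNA content is not visible and a change in many genes is read relative to the rest. The sorted values of any brain array lay within 0.21 log2 units of the mean brain distribution, and those of any liver array within 0.23 of the mean liver distribution, while the mean distributions of the tissues differed by up to 1.42. The tissues therefore appeared to have been normalized apart, and levels were compared within a tissue only. No read depth or signal over background was used for these arrays, and their number limits the precision.

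The value table held 35556 probes with 0 missing values. GEO's platform annotation, which can be old, listed 23099 of them with a gene, 21218 with 1 gene symbol and 1881 with several, and 12457 were unnamed here. Of the probes with 1 symbol, 21185 matched the NCBI RefSeq gene table by Entrez ID, and 0 symbols changed. Where several probes named a gene, the one with the highest mean over all arrays was used, which gave 18820 genes. Within each tissue the 33.3% of genes with the lowest mean over its arrays were left out, below 5.52 in brain and below 3.92 in liver, so that 12547 genes were tested per tissue.

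Haloperidol was compared with placebo in each tissue with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend or robust variances), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The difference between tissues was the contrast of the liver effect with the brain effect in a fit of all 38 arrays in 4 groups, over the 10869 genes kept in both tissues. Before the data were examined, 40 gene lists (pathways, cell types and tissues the dissections could hold) with 573 genes were fixed, of which 495 had a probe with a single name. Lists with at least 3 genes tested were compared with limma's camera at a preset correlation between genes of 0.01, with an estimated correlation and fry beside it. Acute phase genes, blood and leukocytes in brain and blood in liver had fewer genes and were not tested. Array medians and principal components were compared by permutation tests with random resampling.

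The rule for genes named in the text was fixed before the data were examined. It took the 10 largest rises and 10 largest falls past the threshold in each tissue, filled to 10 with the smallest unadjusted p where fewer passed. It also took the 4 members of smallest p of each list whose test passed, up to 4 passing members of any other list, receptors in brain including Drd1, Drd2, Drd3, Drd4, Htr2a and Adra1a, and the enzymes Cyp3a11, Cyp2d22, Cyp2b10 and Cyp1a2 in liver. For the difference between tissues it took the 5 largest in each direction. Adra1a had no probe with a single gene name and was not analysed here.

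The sample titles carry tags of a digit and a letter, and a brain and a liver array share each of 18 tags, although the labels do not say what the tag marks. No arrays of a group were identical, with correlations between them of 0.937 to 0.995 across brain and liver groups. Alternatives covered the filter on dim genes, the normalization, the tag digit or letter as a block, the variance model, array weights, the choice of probes, the arrays in the fit, a Wilcoxon rank sum test and leaving out each array in turn. Covariates for array-wide differences, omission of named arrays and a correction for gene span were added after seeing the data. Each test was also made on 100 random splits of the arrays.

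The fits were tested on simulated data with the real means and spreads, independent genes and 200 changed genes. In brain, the test on 12547 genes recovered 31.3% of the genes changed by 0.25 log2 units, 88.1% of those changed by 0.5 and 100% of those changed by 1, with 8 false calls. In liver, it recovered 14.9%, 70.1% and 95.5% of the same sizes, with 8 false calls. The test of the difference between tissues on 10869 genes recovered 8.96%, 56.7% and 93.9%, with 6 false calls. A list shifted by 0.25 was found in each tissue with both the preset and the estimated correlation, with 0 false lists among the others that share no gene with it. Real list members varied together, with estimated correlations of 0.40 for brain glutamate receptor and 0.60 for liver Kupffer cell genes. The simulation left this out, so its recovery and false calls or lists do not carry over to the real arrays. Plots were drawn with matplotlib 3.10.9.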

Results

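Whole brain and liver were profiled from C57BL/6J mice that carried slow-release pellets of haloperidol, an antipsychotic that blocks dopamine D2 receptors, or placebo for 30 days. Brain arrays came from 10 haloperidol and 10 placebo mice and liver arrays from 9 and 9. Values are log2 expression values normalized by the authors, and changes are haloperidol minus placebo. The precision is limited by the number of arrays.

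Tissue markers matched the labels in each group. In brain, Snap25, a synaptic protein gene, was at 12.80 ± 0.062 (SD, n = 10) with placebo and 12.79 ± 0.047 with haloperidol, and in liver Alb, the albumin gene, was at 13.19 ± 0.029 (SD, n = 9) and 13.22 ± 0.037. Alb in brain lay between 3.93 and 4.51 on 19 of 20 arrays and at 11.11 on the remaining one, haloperidol 4T. Pituitary transcripts also differed between brain arrays: Gh, the growth hormone gene, was at 11.49 in placebo 1L, 10.45 in haloperidol 1R and 10.19 in haloperidol 2N, against a median of 5.15 over all brain arrays. Y-linked transcripts were present in both tissues, with Kdm5d at 8.94 ± 0.16 in placebo and 8.80 ± 0.16 in haloperidol brains, and Xist was at 3.61 ± 0.17 and 3.78 ± 0.31.

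**Figure D1:**
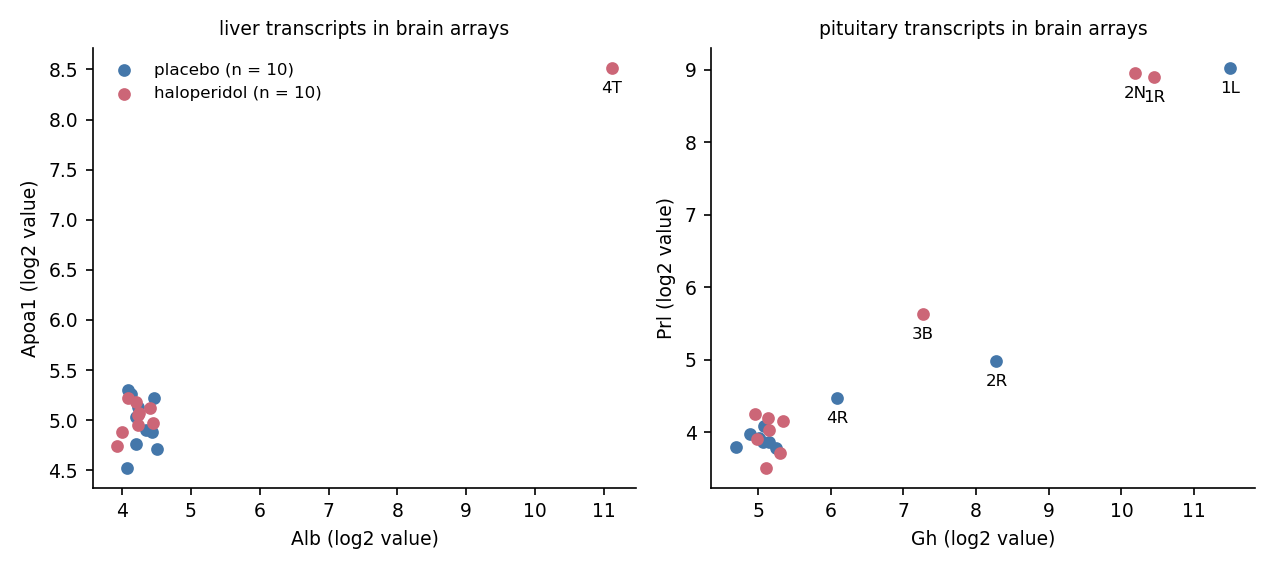
Transcripts of other tissues in the 20 brain arrays, as log2 values of Apoa1 against Alb (left) and of Prl against Gh (right), with 1 point per array coloured by treatment and the tag beside arrays above 6 on the horizontal axis. Haloperidol 4T stands apart for the liver transcripts, with Alb at 11.11, and placebo 1L and haloperidol 1R and 2N for the pituitary ones, with Gh at 10.19 or more.

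The first comparison asked which genes differed in whole brain after chronic haloperidol. Nts, the gene of the neuropeptide neurotensin, rose 2.40-fold, from 6.29 ± 0.31 with placebo to 7.55 ± 0.75 with haloperidol (SD, n = 10 each), and all 10 haloperidol arrays lay above the placebo mean. Genes of mitochondrial proteins were among the other large rises, with log2 changes of 1.14 for Atp5e, a subunit of ATP synthase, 1.07 for Ndufb8, a subunit of complex I, 1.09 for Tomm5, part of the import channel of the outer membrane, and 1.04 for Fmc1. Lyz2, the lysozyme gene of macrophages and neutrophils, rose by 1.06. Of the 10 largest falls, 7 were microRNA genes, led by Mir181b-1 (log2 change -0.83) and followed by Mir708 (-0.77), Mir505 (-0.76), Mir543 (-0.75), Mir491 (-0.75), Mir379 (-0.74) and Mir103-2 (-0.74).

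In all, 3816 of 12547 genes tested passed (limma, Benjamini-Hochberg), 1911 of them higher and 1905 lower with haloperidol. Most changes were small, with a median size of 0.30 log2 units among the genes that passed; 332 exceeded 1.5-fold and 15 exceeded 2-fold. Nts had a standard error of 0.23 and a limma adjusted p of 0.00374. The other large rises were Snora44, a small nucleolar RNA (1.64), the vault RNA gene Vaultrc5 (1.33), AI413582 (1.11) and Zfp931 (1.08), and the other large falls were Snord14e (-0.81), Phxr4 (-0.79) and 4930578G10Rik (-0.76). Adjusted p for these 20 genes ran from 0.00105 to 0.0108 in limma. Vaultrc5 was at 5.10 with placebo, below the brain dim limit of 5.52, and at 6.44 with haloperidol, so it was kept through its haloperidol values.

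The brain arrays differed as a whole along with treatment. The median over all probes was 6.19 ± 0.072 with haloperidol and 6.33 ± 0.044 with placebo (SD, n = 10 each), lower in 9 of 10 haloperidol arrays than the placebo mean (two-sided permutation p = 8e-05, 0.00064 after Benjamini-Hochberg over 8 array measures). The first principal component of the genes tested held 53.2% of the variance, and 9 of 10 haloperidol arrays lay above the placebo mean on it (permutation p = 0.00086, adjusted 0.00344). With the array median, this component or the first component of the dim genes as a covariate, 0 genes passed in limma, with 550, 913 and 3249 genes at an unadjusted p under 0.05. The median size of the 3816 changes was then 0.09, 0.06 and 0.25, but all 3 covariates differ between the groups and can take up an effect of treatment. When the array median was subtracted, 4555 genes passed, 4088 higher and 467 lower, and the median change over all genes moved from -0.02 to 0.12. Without haloperidol 4N and 4T and placebo 1L, 2518 genes passed, of which 2361 were among the 3816, and 17 of the genes named here no longer passed. These were Cat, Cry2, Cyp51, Emcn, Hcrt, Hsp90b1, Htr2c, Idi1, Kcne2, Mal, Me1, Msmo1, P2ry12, Per3, Slc17a7, Sst and Vip.

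**Figure D2:**
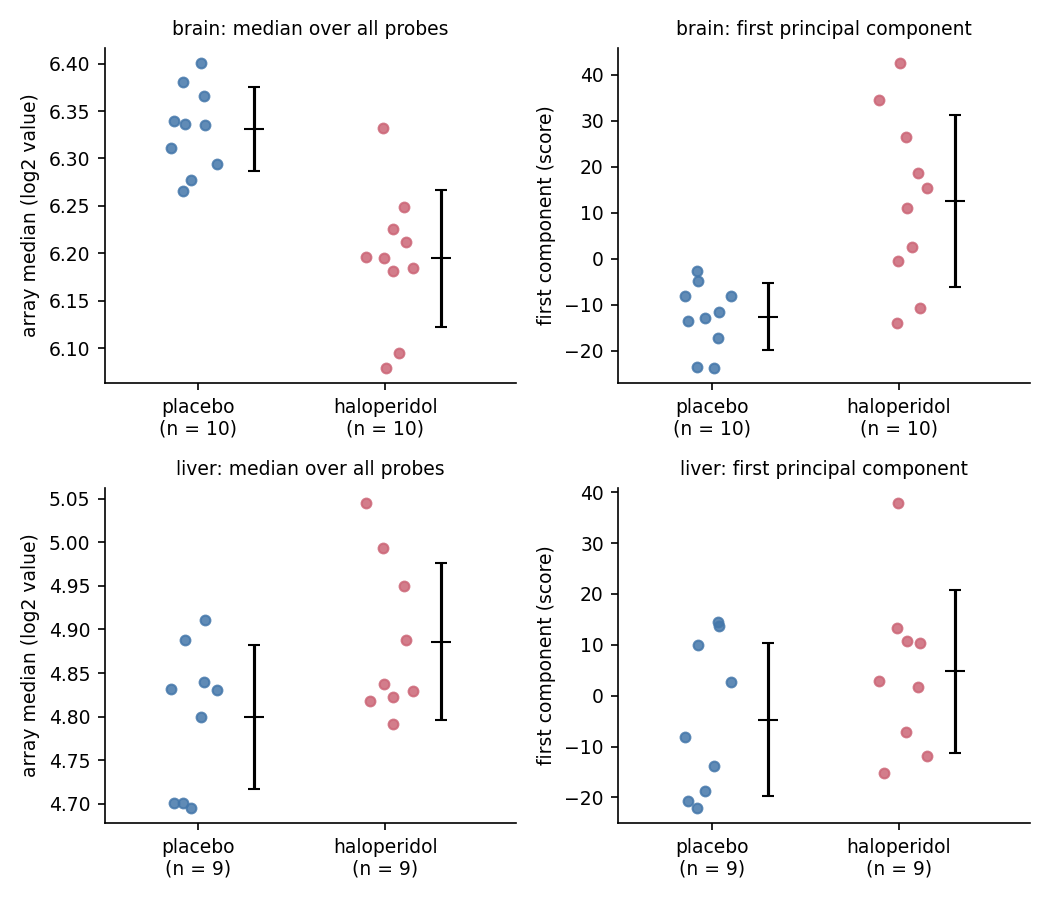
Median log2 value over all probes (left) and score on the first principal component of the genes tested (right) for each brain (top) and liver (bottom) array, with points for arrays and bars for the mean ± SD of each group. The haloperidol brains had lower medians (6.19 against 6.33) and mostly higher scores than the placebo brains, with overlapping ranges, and the haloperidol livers had higher medians (4.89 against 4.80).

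Of the 22 lists tested in brain, 4 passed in camera. Glutamate receptor and postsynaptic density genes fell, with 13 of 21 measured members lower and 0 higher, and 13 lower when adjusted over the list alone. The metabotropic receptor gene Grm7 changed by -0.28 (SE 0.063), the kainate receptor gene Grik1 by -0.29, the AMPA receptor gene Gria2 by -0.27 (SE 0.069) and the NMDA receptor gene Grin2c by -0.42. Camera gave an adjusted p of 0.000858, which became an adjusted p = 0.680 with an estimated correlation. The array median was lower in the same arrays, and with it subtracted 1 of the 21 members passed as lower. Grm7, Grik1 and Gria2 then had limma adjusted p of 0.0625, 0.052 and 0.0836.

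Hypothalamic neuropeptide genes rose, with 7 of 13 measured members higher and 9 higher when adjusted over the list alone or 10 with the array median subtracted. Beside Nts, the vasopressin gene Avp rose by 0.46 (SE 0.13), the orexin gene Hcrt by 0.48 (SE 0.14) and Vip, the gene of vasoactive intestinal peptide, by 0.43 (SE 0.13). The list had a camera adjusted p of 0.00129, and an adjusted p = 0.680 with an estimated correlation. Hcrt was low in 1 placebo array, 1L (6.48 against a median of 7.35 in the other placebo brains), which also carried pituitary transcripts. Without haloperidol 4N and 4T and placebo 1L, Hcrt was at 0.25 and Vip at 0.35 (limma adjusted p 0.0539 and 0.0528), so that the size of the Hcrt change rested largely on these arrays.

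Microglia markers rose, with 6 of 12 measured members higher, also when adjusted over the list alone, and 9 with the array median subtracted. The calcium-binding protein gene Aif1 rose by 0.57 (SE 0.11) and was above the placebo mean in 10 of 10 haloperidol arrays. The adaptor gene Tyrobp rose by 0.75 (SE 0.18), the complement gene C1qa by 0.30 (SE 0.087) and the purinergic receptor gene P2ry12 by 0.38 (SE 0.12). Camera gave an adjusted p of 0.00495, and the list had an adjusted p = 0.680 with an estimated correlation. With the lowest-expressed 50% of genes left out, the neuropeptide and microglia lists had camera adjusted p of 0.077 and 0.0528.

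Circadian clock genes fell, with 5 of 17 measured members lower, and 6 when adjusted over the list alone. Per2, a repressor of the clock, changed by -0.45 (SE 0.092) and lay below the placebo mean in 10 of 10 haloperidol arrays. Arntl, which encodes the activator BMAL1, changed by -0.31, Per3 by -0.34 and Cry2 by -0.20. Camera gave an adjusted p of 0.0377, and the list had an adjusted p = 0.680 with an estimated correlation. The list's mean of -0.14 stayed near its size while its camera adjusted p rose to 0.0527 without placebo 4B (mean -0.13), 0.0639 without haloperidol 4N and 4T and placebo 1L (-0.13) and 0.0588 without the 6 arrays with pituitary transcripts (-0.14). In a fit of all 38 arrays, Per2, Arntl, Per3 and Cry2 had limma adjusted p of 0.0994, 0.391, 0.368 and 0.128. With the array median subtracted, 1 of the 17 genes was lower and 2 were higher. Relative to the median gene, with or without this subtraction, the list means were -0.18 for glutamate receptor, 0.39 for neuropeptide, 0.30 for microglia and -0.12 for clock genes.

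All 4 lists lost their call with each of these 3 array-wide covariates. With the array median as covariate the mean was -0.026 for glutamate receptor, 0.013 for neuropeptide, -0.033 for microglia and -0.098 for clock genes, and with the first component of the genes tested 0.017, 0.094, 0.031 and -0.018. With the first component of the dim genes the means were -0.15, 0.19, 0.17 and -0.16, with camera adjusted p of 0.0808, 0.141, 0.184 and 0.0808. Among the members named here, Hcrt (-0.078), C1qa (-0.039), P2ry12 (-0.0076) and Per3 (0.073) turned direction with the array median, and Tyrobp (-0.0085), Per3 (0.012) and Cry2 (0.027) with the component of the genes tested.

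**Figure D3:**
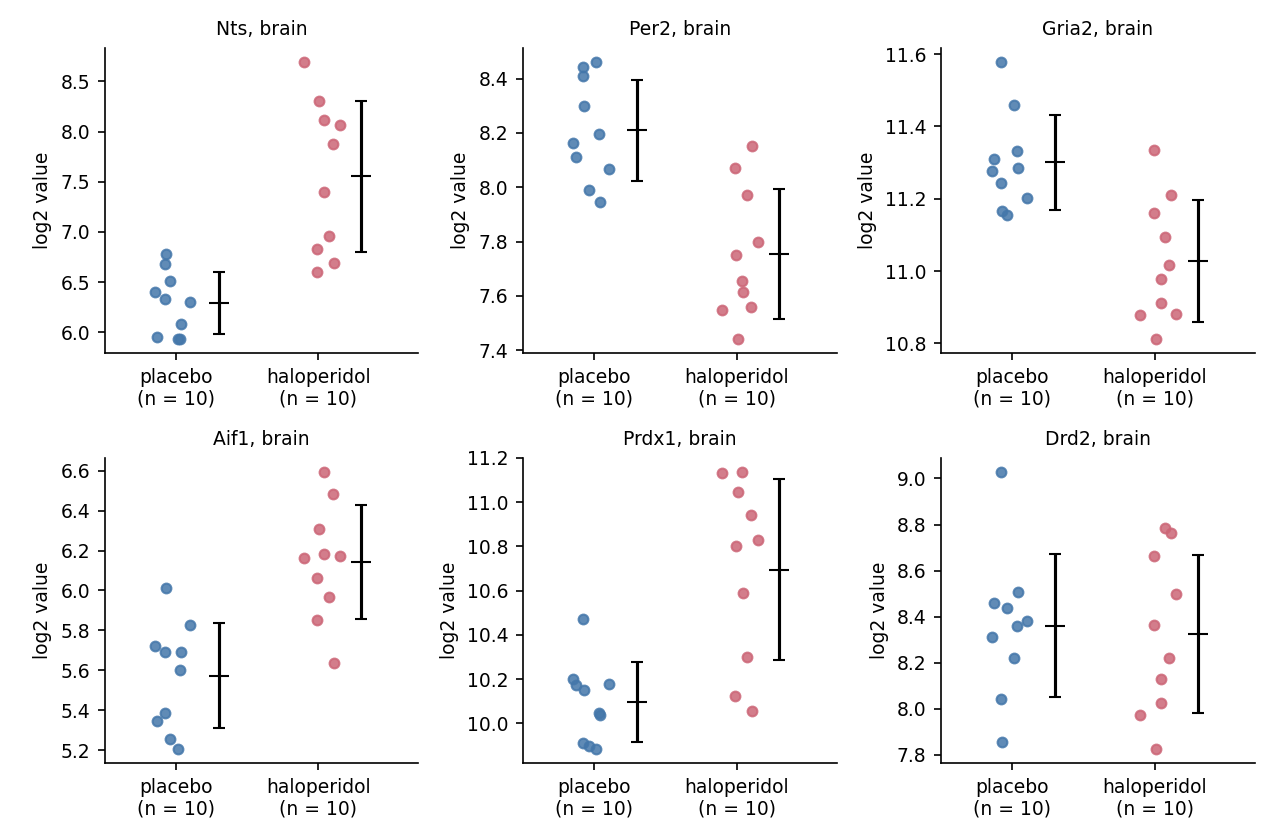
Log2 values of Nts, Per2, Gria2, Aif1, Prdx1 and Drd2 in the brain arrays, with 1 point per array and bars for the mean ± SD of 10 placebo and 10 haloperidol brains. Nts, Aif1 and Prdx1 are higher and Per2 and Gria2 lower with haloperidol, whereas Drd2 overlaps (8.36 against 8.33).

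Haloperidol's receptor genes and the striatal list did not pass. Drd1 changed by 0.02 (SE 0.12), Drd2 by -0.04 (SE 0.13), Drd3 by -0.21 and Drd4 by 0.02, with limma adjusted p of 0.914, 0.855, 0.27 and 0.83. The serotonin receptor gene Htr2a changed by -0.28 (SE 0.11, limma adjusted p = 0.0555), and passed in each of 4 fits that left out 1 array, placebo 1N or 4R or haloperidol 4L or 4T, and under 7 other alternatives such as array weights (0.0142). None of the 20 measured markers of striatal medium spiny neurons passed over all genes or adjusted over the list alone (0 higher, 0 lower), and the camera adjusted p was 0.988. Of these 20, 3 were higher with the array median subtracted, which adds 0.14 to every change. In the dopamine system list (2 of 13 higher, 5 with the array median subtracted, camera adjusted p 0.119), Maoa, which encodes the amine-degrading enzyme monoamine oxidase A, rose by 0.44 (SE 0.11) and the dopamine transporter gene Slc6a3 by 0.50 (SE 0.13). Slc6a3 was low in placebo 1L, at 6.79 against a median of 7.81 in the other placebo brains.

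Other brain lists did not pass as lists but held genes that passed. Among oligodendrocyte and myelin genes (3 of 14 higher, camera adjusted p 0.0579), Opalin rose by 0.70, Aspa by 0.57 and Mal by 0.32, the last with a limma adjusted p of 0.0504 without haloperidol 3B. Among NRF2 targets (3 of 13 higher, 0.119), the peroxiredoxin gene Prdx1 rose by 0.60 (SE 0.13), Nqo1 by 0.65 and the catalase gene Cat by 0.29. Cholesterol synthesis genes (3 of 20 higher, 1 lower, 0.096) held changes both ways, with Msmo1 up by 0.32, Cyp51 by 0.31 and Idi1 by 0.44, and the regulator Srebf2 at -0.20. So did fatty acid synthesis genes (2 of 18 higher, 1 lower, 0.988), with Thrsp at 0.54, Me1 at 0.32 and Acss2 at -0.21. With the array median subtracted, these lists had 10 and 4 members higher and 0 lower, with Srebf2 at -0.068 and Acss2 at -0.072 (limma adjusted p 0.508 and 0.347), and 8 myelin and 8 NRF2 genes were higher. Among interneuron genes (3 of 13 higher, 1 lower, 0.639), Pvalb rose by 0.44 and Sst by 0.29, and Gabrb2 changed by -0.14, a call that ended with the array median subtracted (limma adjusted p 0.999). Choroid plexus genes (2 of 13 higher, 0.119) included Calml4 at 0.79 and Kcne2 at 0.43, both low in placebo 1L. Single members that passed were S100b (0.41) among 12 astrocyte genes, Emcn (0.29) among 10 endothelial genes, Htr2c (0.19) among 8 serotonin and noradrenaline genes, Slc17a7 (-0.20) among 11 excitatory neuron genes and the chaperonin gene Hspe1 (0.74) among 9 heat shock genes. Of 13 unfolded protein response genes, Dnajb9 rose by 0.39 and Hsp90b1 changed by -0.19.

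Adjusted over the list alone, the counts were 3 higher in the myelin, NRF2, cholesterol and interneuron lists, 2 in the dopamine and fatty acid synthesis lists, 1 in the choroid plexus, astrocyte, endothelial, unfolded protein and heat shock lists and 0 in the serotonin and noradrenaline list. On that basis 1 interneuron and 1 fatty acid synthesis gene were lower, and 0 cholesterol, excitatory neuron or unfolded protein genes. Camera adjusted p was 0.233 for endothelial cells, 0.303 for astrocytes, 0.543 for excitatory neurons, 0.894 for the unfolded protein response, 0.932 for the serotonin and noradrenaline system and 0.988 for heat shock. Immediate early genes (0 of 18, 0.152), cell cycle genes (0 of 5, 0.639), cerebellar markers (0 of 11, 0.639) and pituitary markers (0 of 3, 0.894) held no gene that passed. Subtraction of the array median gave as higher 6 astrocyte, 4 choroid plexus, 3 endothelial, 3 interneuron, 2 cell cycle, 2 unfolded protein, 1 heat shock and 1 serotonin or noradrenaline gene, with 0 lower in these lists, and 0 excitatory neuron, immediate early, cerebellar or pituitary genes passed. Mean and median differed in sign for the heat shock (0.056 and -0.031), fatty acid synthesis (0.027 and -0.020) and interneuron (0.067 and -0.0074) lists. The calls of Sst, Gabrb2, Slc17a7, Kcne2 and Srebf2 each ended in 14 of the 20 fits that left out 1 array, those of Hsp90b1 in 13, Htr2c in 10, Cry2 in 6 and Idi1 in 4.

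**Figure D4:**
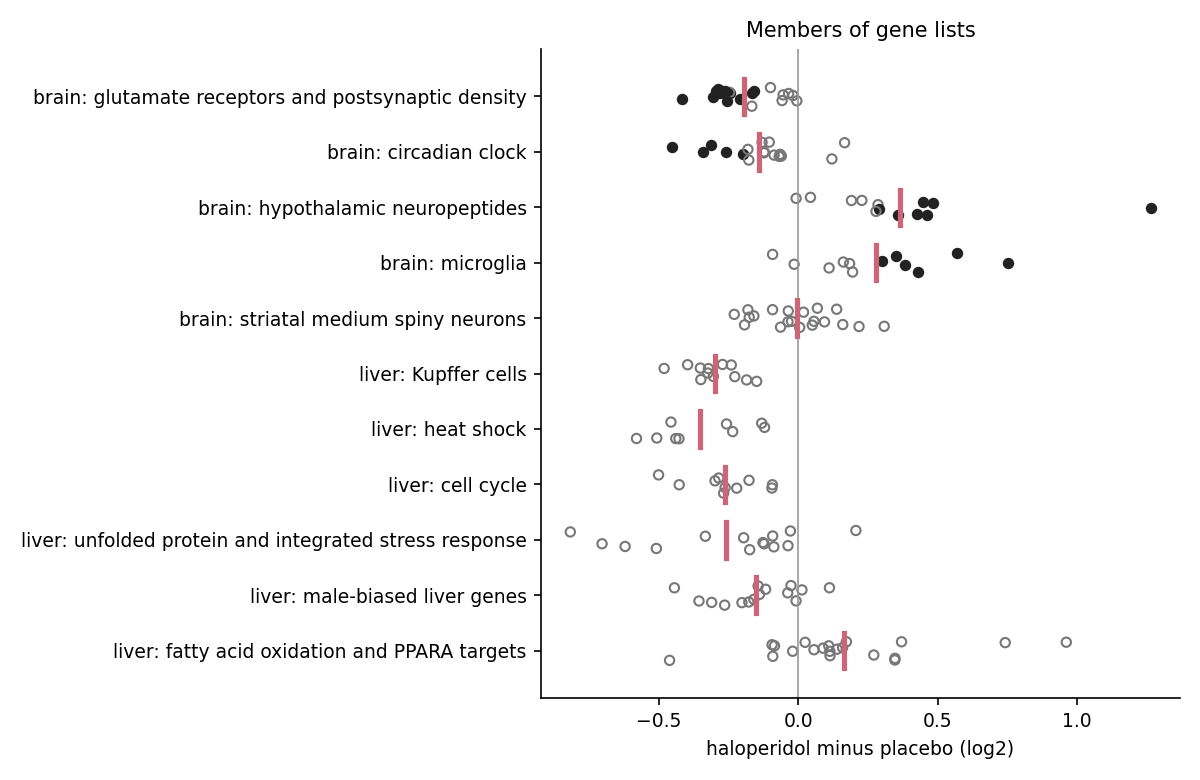
Log2 change (haloperidol minus placebo) of each measured member of gene lists in brain and liver, with filled points for genes whose limma adjusted p is under 0.05 in that tissue, open points for the others and a vertical bar at the list mean. In brain 13 of 21 glutamate receptor and postsynaptic density genes are filled and lower, 0 of 20 striatal genes are filled, and in liver 0 genes of any list are filled.

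The second comparison asked the same of liver, where single genes did not pass. The 10 genes of smallest unadjusted p were led by Rhbg, an ammonium transporter gene, at -0.67 (SE 0.12), and held 2 tubulin genes, Tubb4b at -0.39 (SE 0.082) and Tuba1b at -0.38 (SE 0.082). Lower values were also measured for Nans (-0.46), Ttll1 (-0.54), Bmp7 (-0.49), Gtf2e1 (-0.33) and Nudt5 (-0.29), and higher ones for the vitamin C transporter gene Slc23a2 (0.40) and Mapk1ip1 (0.38). The drug-metabolising enzyme genes Cyp3a11 (-0.02, SE 0.068), Cyp2d22 (0.02, SE 0.071), Cyp2b10 (-0.21, SE 0.35) and Cyp1a2 (-0.11, SE 0.081) differed by less than the threshold requires, with limma adjusted p of 0.947, 0.927, 0.86 and 0.615.

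In limma 0 of 12547 liver genes passed, the smallest adjusted p being 0.251, while 1316 had an unadjusted p under 0.05 where 627 are expected by chance on average. Genes vary together, so the count by chance can lie far from that average, and the excess was not tested. The Wilcoxon test also gave 0, with 1126 genes at an unadjusted p under 0.05, a fit of all 38 arrays gave 40, and the first component of the residuals as a covariate gave 28. Neither of the last 2 fits alters a log2 change, only its variance. Without haloperidol 1B, 1 gene passed, Rhbg, at -0.76 (limma adjusted p = 0.00727).

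The liver array median was 4.89 ± 0.090 with haloperidol and 4.80 ± 0.082 with placebo (SD, n = 9 each), opposite in sign to brain and higher than the placebo mean in 8 of 9 haloperidol arrays (two-sided permutation p = 0.0491, 0.0982 after Benjamini-Hochberg). Of the 24 lists tested in liver, 6 passed in camera, although 0 of their members passed over all genes. Kupffer cell markers, genes of the liver's resident macrophages, had a mean change of -0.30 over 12 members, and 8 were lower when adjusted over the list alone. They included the complement genes C1qc (-0.35, SE 0.10), C1qa (-0.30, SE 0.096) and C1qb (-0.32, SE 0.11) and the macrophage receptor gene Adgre1 (-0.40, SE 0.14). The camera adjusted p of 7.19e-07 became an adjusted p = 0.605 with an estimated correlation. Cell cycle genes had a mean change of -0.26 over 10 members, with Rrm2 at -0.50, Top2a at -0.26, Mcm6 at -0.27 and Ccna2 at -0.22, and 3 were lower when adjusted over the list alone. Their camera adjusted p was 0.000136, and this list alone also passed with an estimated correlation (adjusted p = 0.0429). Top2a (4.35 with placebo, 4.09 with haloperidol) and Ccna2 (4.30, 4.08) lay below the array medians given above and close to the dim limit of 3.92. Mcm6 (5.26, 4.99) and Rrm2 (5.97, 5.47) lay above those medians.

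Heat shock genes had a mean change of -0.35 over 9 members, with Hspb1 at -0.58, Hspa4l at -0.51, Hsp90aa1 at -0.44 and Hspe1 at -0.23, and 0 were lower when adjusted over the list alone. Their camera adjusted p of 0.000122 became an adjusted p = 0.611 with an estimated correlation. Genes of the unfolded protein and integrated stress response had a mean change of -0.26 over 14 members, with Asns, the asparagine synthetase gene, at -0.82, Creld2 at -0.70, Sdf2l1 at -0.62 and the chaperone gene Hspa5 at -0.33, and 4 were lower when adjusted over the list alone. Camera gave an adjusted p of 0.00477, and there was an adjusted p = 0.611 with an estimated correlation. Male-biased liver genes had a mean change of -0.15 over 15 members (Ugt2b38 -0.44, Selenbp2 -0.36, Cyp7b1 -0.31, Cyp4a12b -0.26), with 0 lower when adjusted over the list alone, a camera adjusted p of 0.0125 and an adjusted p = 0.611 with an estimated correlation.

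Fatty acid oxidation genes and PPARA targets had a mean change of 0.16 over 20 members, with Fgf21, a fasting hormone gene, at 0.37, Acot3 at 0.74, Angptl4 at 0.27 and Cyp4a14 at 0.96 (SE 0.49), and 1 was higher when adjusted over the list alone. Fgf21 (4.23 with placebo, 4.60 with haloperidol) lay below the liver array medians and close to the dim limit of 3.92. Camera gave an adjusted p of 0.0019, and there was an adjusted p = 0.664 with an estimated correlation. With the tag digit as a block the list no longer passed (mean 0.10, camera adjusted p 0.0667). The brain transcripts Snap25 and Camk2a were raised in liver arrays haloperidol 2T (4.40 and 3.88) and 3B (4.71 and 4.37), against medians of 3.40 and 3.32. Without these 2 arrays, 3 lists passed, and the PPARA, male-biased and unfolded protein lists had camera adjusted p of 0.0555, 0.0595 and 0.0535. The means of these 3 lists that lost their call were then 0.14, -0.11 and -0.19, against 0.16, -0.15 and -0.26 with all liver arrays. The male-biased list also had a camera adjusted p of 0.17 after quantile normalization anew (mean -0.12), and of 0.126 without haloperidol 2T and 0.05004 without placebo 3T.

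The other liver lists did not pass in camera, with adjusted p of 0.118 for female-biased genes, 0.655 for acute phase, pancreatic and fatty acid synthesis genes, 0.667 for stellate cells and 0.837 for immediate early, cholesterol synthesis and bile acid genes. Glucose metabolism and the CAR and PXR targets were at 0.878, cholangiocytes at 0.947, the circadian clock, leukocytes, growth hormone signalling and adipose tissue at 0.949, and AHR targets, NRF2 targets and endothelial cells at 0.974. Adjusted over the list alone, 1 female-biased gene and 1 CAR or PXR target were higher.

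The third comparison tested whether the effect of haloperidol differed between the tissues. The genes that differed most with a lower effect in liver were Snora44 (liver minus brain -1.62, SE 0.33), Lyz2 (-1.41), Vaultrc5 (-1.39), Atp5e (-1.37) and Zfp931 (-1.36), each of which rose in brain. Those with a higher effect in liver were 4930578G10Rik (1.32), Mir505 (1.28), Snord14e (1.23) and Mir30e (1.20), each of which fell in brain, and Rgs16, a regulator of G protein signalling, at 1.19 (SE 0.43), with a change of 1.20 in liver (limma adjusted p = 0.391) and 0.02 in brain. In all, 2502 of 10869 genes differed (limma, Benjamini-Hochberg), 996 with a higher and 1506 with a lower effect in liver. The array medians differed in opposite directions in brain and liver, and this test was not made with array-wide covariates. The 2502 calls can therefore not be told apart from the array-wide difference of the brain arrays. Of the 3407 genes that changed in brain and were kept in both tissues, 2020 differed from liver and 767 had a change of the same sign in liver. Without the brain arrays haloperidol 4N and 4T and placebo 1L, 1568 genes differed, and Zfp931, 4930578G10Rik and Rgs16 no longer passed (limma adjusted p 0.074, 0.0666 and 0.0597). Their differences were then -1.36, 1.10 and 1.25.

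The changes in brain and liver were also set against each other across genes. Over 10869 genes and the 18 tags with both tissues, Pearson's r was -0.377 and Spearman's rho -0.404, so that genes higher in haloperidol brains tended to have lower values in haloperidol livers. Genes are not independent replicates. In 100 random reassignments of treatment to tags, r ran from -0.48 to 0.35, and the two-sided permutation p was 0.0891 for r and 0.0693 for rho, so that chance could not be excluded for the relation.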

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

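Of the tests reported here, the comparison of the other haloperidol arrays with placebo was chosen after the result was seen. In 266 sets of 9 or 10 values (named genes, tissue markers, sex-linked genes and array medians per group), 31 had an array far from the others, where chance gives about 1 in 20 sets.

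In brain haloperidol 4T, the liver transcripts Alb (11.11 against a median of 4.23 in the other 9), Apoa1 (8.52 against 5.05), Fgb (7.43 against 3.64) and Cps1 (6.58 against 4.46) stood far above the group. Liver RNA carried into this sample is a candidate explanation, since 50 of the 50 genes with the largest excess in liver had their highest brain value in this array, by a median of 1.90 log2 units over placebo. A liver sample under a brain label is argued against by the 50 genes with the largest excess in brain, whose median in 4T was 0.039 above brain placebo, while liver lay at -8.51. Induction of liver genes in brain by haloperidol is argued against by the other 9 haloperidol arrays, whose median over the 50 liver genes was 0.033 above placebo. The step at which such RNA would have entered stays open.

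Placebo 1L held 9 of the other outlying brain values. It was low for the choroid plexus genes Ttr (10.99 against 12.30), Calml4 (5.10 against 6.16) and Kcne2 (5.26 against 6.24), for Slc6a3 (6.79 against 7.81), Pvalb (9.37 against 10.60), Hcrt (6.48 against 7.35), S100b (8.74 against 9.66) and Nqo1 (5.39 against 6.31), and high for Drd3 (7.91 against 6.60). Other placebo brains stood apart for Mir505 (1N, 9.51), P2ry12 (1N, 6.01), Vip (4B, 7.56), Mal (4R, 10.54) and Arntl (4R, 7.90).

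Among haloperidol brains, 1R was low for Opalin (7.22) and high for Hsp90b1 (11.001), 4N was low for Per3 (7.31), and 4T was high for Drd3 (6.99) and low for Eif2s3y (8.77). In liver, haloperidol 2T was low for Cyp4a12b (11.10), Eif2s3y (7.95) and Uty (6.35), haloperidol 2N was high for C1qc (7.96) and 1R for Cyp3a11 (12.24). Placebo 3L was low for Hspb1 (7.57) and Cyp3a11 (11.67), and placebo 1T for Fgf21 (3.82).

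The effect of haloperidol differed between liver and brain for 2502 genes by the test of the difference itself (limma). That test was not made with array-wide covariates, so these calls are not separated from the array-wide difference of the brain arrays. The named differences, liver minus brain, were Snora44 -1.62, Lyz2 -1.41, Vaultrc5 -1.39, Atp5e -1.37 and Zfp931 -1.36, and 4930578G10Rik 1.32, Mir505 1.28, Snord14e 1.23, Mir30e 1.20 and Rgs16 1.19. Outside the genes tested, 3152 of 8233 brain probes without a single gene name passed when every probe of the table was tested, and 25.6% of these were higher with haloperidol.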

How the results depend on the processing

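The covariates other than the residual component, the omission of named arrays and the correction for gene span were tests chosen after the result was seen, and the cause of a change was not tested unless stated. Of 988 values of named brain genes under the alternatives set before the data were examined, single arrays left out aside, 924 kept their direction and side of the threshold, 57 lost and 7 gained the call, and 0 reversed. Several of these alternatives leave a log2 change as it is, such as the filters on dim genes, the variance models, the fit of all 38 arrays and the Wilcoxon test. The 0 reversals were thus partly fixed in advance, and the added covariates lie outside this count. Of the 57 losses, 17 came in a fit of all 38 arrays (Per2 0.0994, Thrsp 0.0857 and Dnajb9 0.0996 among them), 11 with the array median subtracted, 7 without a filter on dim genes and 7 in the Wilcoxon test, and Htr2a accounted for the 7 gains. For the named liver genes it was 547 of 564, with 17 gaining a call, and for the differences between tissues 56 of 60. The counts of changed brain genes ran from 2869 to 4817 when single arrays were left out, and the lists from 3 to 6. In liver these ranges were 0 to 1 and 5 to 7.

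In brain, 5754 genes passed with the first component of the residuals as a covariate and 7771 probes when every probe of the table was tested, which tests more features. The residual component comes from values centred within each group. In either tissue it therefore left the log2 changes unaltered and changed only their variances, so a higher count with it is not a larger effect. The added covariates gave 0 genes each (first component of the genes tested, of the dim genes, and the array median), and without haloperidol 4N, 4T and placebo 1L the count was 2518. The brain lists were 2 with the lowest-expressed 50% of genes left out, which removes members, 4 with fry, 0 with an estimated correlation and 0 with the component of the dim genes. All 4 lists named for brain lost their call with each of the 3 added covariates. With the component of the dim genes the means moved least, from -0.20 to -0.15 for the glutamate and from -0.14 to -0.16 for the clock list (camera adjusted p 0.0808 each). The neuropeptide mean still went from 0.37 to 0.19 and the microglia mean from 0.28 to 0.17 (camera adjusted p 0.141 and 0.184). With the first component of the genes tested, the camera adjusted p was 0.581 for the glutamate, 0.157 for the neuropeptide, 0.732 for the microglia and 0.786 for the clock list, and with the array median 0.972, 0.903, 0.734 and 0.14, while 3 other lists passed with each. In liver, the unfolded protein and male-biased lists lost their call with the first component of the genes tested (0.086 and 0.451) and with the array median (0.184 each), the PPARA list with the tag digit as a block (0.0667) and the male-biased list after quantile normalization anew (0.17). In liver, 28 genes passed with the first component of the residuals and 40 in a fit of all 38 arrays, and lists were 1 with an estimated correlation, 1 with fry and 3 without haloperidol 2T and 3B. The difference between tissues gave 1568 without the 3 brain arrays.

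A brain and a liver array share each of 18 tags. Own-tag deviations from the group means correlated at -0.32 to 0.25 (median 0.0011), 5 of 18 over 0.1, and 0 arrays correlated best with their own tag, so the data gave no hint of pairing. With the tag as a fixed replicate block, 1752 genes differed between tissues and Rgs16 no longer passed (adjusted p 0.0587). With it as a random block, 2364 differed and Zfp931 no longer passed (0.0554). These blocks changed no other named call.

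Several brain changes turned direction, none passing then. With the first component of the genes tested as covariate these were Tomm5 -0.037, Zfp931 -0.011, Slc17a7 0.027, Kcne2 -0.13, Aspa -0.087, Mal -0.083, Tyrobp -0.0085, Msmo1 -0.037, Cyp51 -0.0076, Idi1 -0.13, Srebf2 0.049, Thrsp -0.010, Me1 -0.040, Per3 0.012, Cry2 0.027, and the glutamate list's mean was 0.017. With the array median as covariate they were Phxr4 0.00061, Mir708 0.015, Mir505 0.046, Mir379 0.036, Htr2c -0.022, Sst -0.098, Hcrt -0.078, Kcne2 -0.070, Mal -0.016, C1qa -0.039, P2ry12 -0.0076, Msmo1 -0.064, Cyp51 -0.068, Cat -0.029, Per3 0.073, the microglia list's mean was -0.033, and the glutamate list's test turned while its mean stayed at -0.026. Correlations of brain and liver changes ran from -0.413 to -0.291. Dim genes limit the test, as no signal over background was used.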

Other observations

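Of the tests reported here, those of the gene families, of the array-wide axis, of the covariates for Nts and of the random splits were chosen after the result was seen, and that of the hypothalamic covariate before. Genes of protein synthesis and energy supply rose together in the haloperidol brains. Of 65 cytosolic ribosomal protein genes 59 were higher and 0 lower, with a mean change of 0.42, and of 71 mitochondrial ribosomal protein genes 49 were higher (mean 0.37). The respiratory chain followed, with 27 of 34 complex I subunits (mean 0.42), 12 of 13 cytochrome c oxidase subunits (0.38) and 13 of 17 ATP synthase subunits (0.41) higher and 0 lower. So did 14 of 15 proteasome core subunits (0.44) and 12 of 20 histone genes (0.40). MicroRNA genes moved the other way, with 76 of 114 lower, 2 higher and a mean of -0.39, while small nucleolar RNA genes went both ways (6 higher, 9 lower of 45, camera adjusted p 0.62). Camera adjusted p over the 10 families was 2.54e-24 for cytosolic ribosomal proteins, 1.35e-17 for mitochondrial ones and 1.22e-18 for microRNA genes. For the respiratory chain, proteasome and histone families it ran from 2.11e-15 (complex I) to 1.16e-08 (cytochrome c oxidase). With an estimated correlation each of these families had an adjusted p = 0.117, so none passed. Subtracting the array median adds the same amount to every brain change, so it cannot turn a rising family, and it took the small nucleolar RNA genes from a mean of -0.011 to 0.12. The microRNA genes stayed lower under it (mean -0.25, 61 of 114 lower, 4 higher). The families were not tested with the array-wide covariates, with each of which 0 single brain genes passed. Whether the family changes are separate from the array-wide difference was therefore not tested. With the array median as covariate, Mir708 (0.015), Mir505 (0.046) and Mir379 (0.036) turned direction. The other microRNA genes among the largest falls kept theirs. Across genes, a longer gene span went with a lower change (Spearman's rho -0.27; genes are not independent replicates). With each array's trend over span removed, 45 cytosolic ribosomal protein genes were higher and 1 lower (mean 0.29), 26 of 34 complex I subunits were higher (0.34), 56 microRNA genes were lower and 6 higher (-0.19), and small nucleolar RNA genes had a mean of 0.17 (17 higher, 6 lower). The small nucleolar RNA family then passed as higher in camera (adjusted p 0.00313), though not with an estimated correlation (adjusted p 0.0971).

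In liver, where the array median differed in the opposite direction to brain (0.086), the mean changes had the opposite sign for several of these families, with 0 members passing in limma. Complex I subunits were at -0.15, mitochondrial ribosomal proteins at -0.14, proteasome core subunits at -0.14 and ATP synthase subunits at -0.13, with camera adjusted p of 8.17e-09, 5.17e-09, 0.000271 and 0.000276 and an adjusted p = 0.204 with an estimated correlation for each. The smallest p in brain belonged to Alas2, the erythroid enzyme gene of haem synthesis, chosen here after its value was seen. It rose 1.80-fold (log2 change 0.85, SE 0.11, limma adjusted p 0.00105), with 10 of 10 haloperidol arrays above all placebo arrays, and its change in liver was -0.28 (adjusted p 0.362).

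The breadth of the brain change follows an axis on which arrays also vary within groups. An axis of array-to-array variation that needs no haloperidol is a candidate explanation: the leading component of the 10 placebo arrays alone, with 34.5% of their variance, correlated with the haloperidol changes across 12547 genes at 0.542 in size. Differences between random sets of 5 haloperidol arrays each correlated with that component at a median of 0.294 and at most 0.544. The leading component of the haloperidol arrays alone correlated with the haloperidol changes at 0.860 in size, and that of the residuals of both groups at 0.883. Both include haloperidol arrays and can carry a graded response to haloperidol. With the first component of the dim genes as covariate, the median size of the 3816 changes moved from 0.30 to 0.25 and their median standard error from 0.088 to 0.12, while several of the largest falls lost most of their size (Mir379 from -0.74 to -0.23, Mir491 from -0.75 to -0.26, Mir708 from -0.77 to -0.26 and Phxr4 from -0.79 to -0.30). The array median took the median size to 0.09. Unequal distributions left by the normalization are argued against as the whole cause, since 3372 of the genes passed again after quantile normalization anew, and gene length likewise as the whole cause, since 3053 passed again with each array's trend over gene span removed. Whether the axis is RNA quality, dissection or a graded response to haloperidol stays open.

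Whether the rise of Nts is partly separate from that axis was not settled. Within the haloperidol brains, Nts was lowest where the score on the first component of the genes tested was lowest, in 1R (6.60, score -14.0) and 4L (6.69, -10.8). It was highest where that score was highest, in 3B (8.70, 34.6) and 4N (8.30, 42.6). In 1R and 4L, Nts lay below the highest placebo value (6.78). With 3 array-wide covariates its log2 change was 1.34 (95% interval 0.694 to 1.996, dim genes), 0.82 (0.11 to 1.54, array median) and 0.38 (0.04 to 0.73, genes tested), against 1.26 without. These intervals are unadjusted. Its limma adjusted p over all genes was 0.111, 0.919 and 0.668 in the same order, so Nts passed with none of them. In size, 2 of the covariates left more of the rise than the third. That one is computed from the genes tested and can carry the effect of treatment itself, and all 3 differ between the groups, so the axis and haloperidol cannot be told apart here. With the mean of the 12 other hypothalamic neuropeptides as covariate, Nts still rose by 0.85 (0.32 to 1.39), so a shared rise of these genes did not account for all of it. Their mean is an inexact measure of hypothalamic content, as Vip and Sst among them are also on the interneuron list. More hypothalamic tissue in the haloperidol samples is therefore not excluded. The largest change among those 12 was 0.48. A response of Nts to haloperidol stays open as a hypothesis.

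Among 100 splits of the brain arrays, 1, the real one, gave as many as 3816 genes. Chance is unlikely by this count but not excluded, since the highest other split gave 3703. That split parted the arrays nearly as far on the first component (24.6 against 25.3). For the brain lists, 75 of 100 splits gave at least 4, with up to 13, so chance cannot be excluded for the number of lists. In liver, where the real count was 0, all 100 of 100 splits necessarily gave as many genes, so this count says nothing about chance. The highest other split gave 727, and 2 of the 100 gave any gene. For the liver lists, 30 of 100 splits gave at least 6, with up to 10, and chance cannot be excluded. For the difference between tissues, 1 of 100 reassignments, the real one, gave as many as 2502 genes and the highest other 1122. Chance is unlikely by this count, although 100 reassignments cannot exclude it.

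Pituitary transcripts were present in some brain arrays of both groups. Prl, the prolactin gene, was at 9.03 in placebo 1L, 8.95 in haloperidol 2N and 8.90 in haloperidol 1R, against a median of 4.06 over all brain arrays, and Gh was at 8.28 in placebo 2R, 7.26 in haloperidol 3B and 6.09 in placebo 4R. Without these 6 arrays 3467 brain genes passed, while the clock list (mean -0.14, camera adjusted p 0.0588) and 7 named genes no longer did, with changes near their former size (Cry2 -0.18, Emcn 0.24, Gabrb2 -0.16, Htr2c 0.22, Kcne2 0.35, Slc17a7 -0.17 and Srebf2 -0.19).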
